A study of Homo sapiens with 60 samples.

How the data were processed

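RNA sequencing was done in 60 libraries of the human multiple myeloma cell lines JJN3 and U266. Each line was treated with vehicle, panobinostat (an HDAC inhibitor), 5-azacytidine (a DNMT inhibitor), 5-azacytidine followed by panobinostat (called the combination here) or N-methyl-2-pyrrolidone (NMP), for 4 h or 24 h, with 3 libraries in each of the 20 groups. Per the labels' protocols, 5-azacytidine groups were pre-treated for 24 h and harvested after a further 4 h or 24 h, and combination groups received panobinostat after the same pre-treatment. Doses are not given in the sources used here. The 4 treatments of a line and time share the same 3 vehicle libraries. JJN3 was grown in a DMEM and Iscove mixture and U266 in RPMI, both with fetal bovine serum, so a difference between the lines includes a difference of medium. Titles without a letter were called replicate A. The labels do not say whether replicates A, B and C were separate cultures, so the p-values given here measure the spread among samples and that spread may be technical.

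Per the submitters' processing notes, base calls came from CASAVA 1.8.2, reads were checked with FastQC, aligned to GRCh37 with TopHat2 2.0.8b and counted per gene with HTSeq 0.5.3p9, and the counts were transformed with limma 3.14.4. The gene annotation release and the scaling method are not given in the sources used here. The deposited matrix holds log2 CPM (counts scaled to a common library total), which the authors made with an added count of 0.5 per gene. It has 17998 genes in 60 columns, and columns not mapped to a sample numbered 0. Solving the transform back gave whole counts for 100% of values at a tolerance of 0.001. Totals ran from 16146919 to 22598327 counts per library, and the scaling factors implied by the values ran from 0.8652 to 1.2002. The matrix had already been restricted upstream, since every gene in it had more than 1 CPM in at least 2 libraries. The 10 most abundant genes took 3.87% to 11.21% of counts. A level of 3 counts, the floor used here, was 0.133 to 0.195 CPM. Gene names were joined by identifier for 17380 genes (96.6%). The reference used here is a different genome build from the alignment, so it served for names and no positions were used. The library kit keeps no strand, so values of overlapping and antisense genes, and of near-identical paralogs such as HBG1 and HBG2 or members of the MAGE families, are uncertain.

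The main test was limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a trend on mean level, a mean for each of the 20 groups over the 60 libraries, and genes at log2 CPM of at least 0 in at least 3 libraries. This left 17464 genes and removed 534. The fit had 40 residual degrees of freedom and a median prior of 6.2. Adjusted p-values are Benjamini-Hochberg values within each comparison, and a gene is called at an adjusted p under 0.05. There were 40 comparisons: 16 of a treatment against vehicle, the combination against panobinostat in each line and time, the combination effect minus the sum of the effects of panobinostat and 5-azacytidine (the non-additive effect), U266 minus JJN3 for each effect, and 24 h minus 4 h for each effect. The median standard error was 0.268 log2 units for a comparison of 2 groups and 0.379 for a difference of effects. Log2 changes are followed by their standard error (SE) and compare means of 3 libraries with means of 3 libraries. Since log2 values at very few counts depend on the added 0.5, a gene with a group at 0 counts is given as a smallest fold above the floor, and a gene with a group at 1 to 3 counts as a ratio with its 95% counting interval, which holds counting error alone. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Deposited raw reads were not used here.

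Simulated data with counts drawn around the levels of the JJN3 4 h NMP and vehicle groups, with 200 of 17484 genes changed, were tested in the same way. Recovery was 24% at 1.5-fold, 60% at 2-fold, 90% at 4-fold and 96% at 8-fold, with 50 genes at each. Of 159 calls, 24 (15.1%) were unchanged genes, and 16 of these 24 had a control level under 0 log2 CPM. A 10% limit set for this share was not met. Recovery and list tests were passed, but simulated no inter-gene correlation, so its preset was untested. The share was 9.2% of 152 calls with only the libraries of the cell line in the fit and 10.8% of 158 calls with voom weights. The main test was kept because the design was fixed, so the false share of calls at low levels is above the nominal 5%.

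Replicate letters were tested for pairing over 10427 genes with a mean of at least 2 log2 CPM. A comparison counted as paired where every correlation between the differences of a letter was over 0.1. This held in 12 of 16 comparisons with vehicle (correlations 0.17 to 0.74) and in the 4 of the combination with panobinostat (lowest 0.24), and not in the 4 with JJN3 at 24 h (lowest -0.12). A replicate block is therefore fitted as an alternative, and Results print its count where the pairing holds and it changed by more than 1.5-fold. Counts are also given without a library where leaving it out moved them by more than 1.5-fold.

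A total of 33 gene lists fixed in advance were tested with camera at a preset inter-gene correlation of 0.01 in the 16 comparisons with vehicle, 528 tests adjusted together. The lists were the plasma cell identity genes, MYC-driven ribosome biogenesis, MYC-driven metabolism, S phase, G2 and mitosis, CDK inhibitors, p53 pathway targets, the BCL2 family in pro-death and pro-survival members, ER chaperones and the unfolded protein response, the integrated stress response, the heat shock response, oxidative stress and metallothioneins, immediate early genes, NF-kappaB targets, the type I interferon response, HLA class I and HLA class II presentation, cholesterol synthesis, histone deacetylases, bromodomain proteins, genes commonly raised by BET bromodomain inhibitors, polyadenylated and linker histones, DNA methylation machinery, pyrimidine nucleoside handling, cancer-testis and germline genes, neuronal genes with REST binding sites, markers of other cell types (erythroid, myeloid, mature B, T and NK, stromal and epithelial) and mitochondrially encoded mRNAs. The tests were repeated with a correlation estimated from the data and with fry. Counts of members that rose or fell use the adjustment over all genes, and counts adjusted over the list alone are given beside them.

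Named genes follow a fixed rule. Not every gene under it is given. Part a is a panel with MYC, IRF4, IKZF1, IKZF3, PRDM1, XBP1, SDC1, TNFRSF17, CD38, CRBN, CCND1, CCND2, MAF, CDKN1A, BCL2L11, BMF, MCL1, HEXIM1, DNMT1 and HMOX1. Part b takes, for each treatment and time, the 4 largest rises and the 4 largest falls among protein-coding genes called in both lines in the same direction with every treated library beyond every control library, ranked by the smaller change, without names of clones, open reading frames, pseudogenes or antisense transcripts. Part c takes, for the called lists described, members among the 4 with the smallest adjusted p. Not every list called by camera is described in every comparison. Part d takes, for the other comparisons, the 3 largest positive and the 3 largest negative estimates among called genes with the same name filter.

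Alternatives planned at the start were no level filter, a stricter filter (mean of at least 1 CPM), median centring, quantile normalization, robust and constant priors, the replicate block, only the 30 libraries of a line, a 2-fold minimum, leaving out each library, an estimated correlation and fry. Added after the data were seen were voom weights on recovered counts, only the libraries compared (for the JJN3 24 h combination), replicates A and B alone, and the replicate block with an estimated correlation for the lists. A count-based tool was planned for a file of counts, and pseudocounts of 0.1 and 1 for a file of CPM. The file holds log2 values and neither was run, although the recovered counts would have allowed them. The libraries of each comparison were also regrouped and the calls counted again.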

Results

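Gene expression was measured in JJN3 and U266 myeloma cells, in 3 libraries for each of 20 groups. The cell line was the largest source of variation: the first principal component over the 60 libraries held 71.8% of variance and separated JJN3 from U266, and the second held 9.6%. Within a line, the first component held 37.9% in JJN3 and 47.4% in U266 and set the 24 h libraries of panobinostat, the combination and NMP apart from vehicle. The 3 libraries of the JJN3 24 h combination lay further apart than those of any other group, with a median SD of 0.385 log2 units over genes against 0.116 to 0.244 in the other 19 groups. Every one of the 60 replicate pairs differed beyond counting noise, with a chi-square per gene of 9.08 to 222.12.

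**Figure D1:**
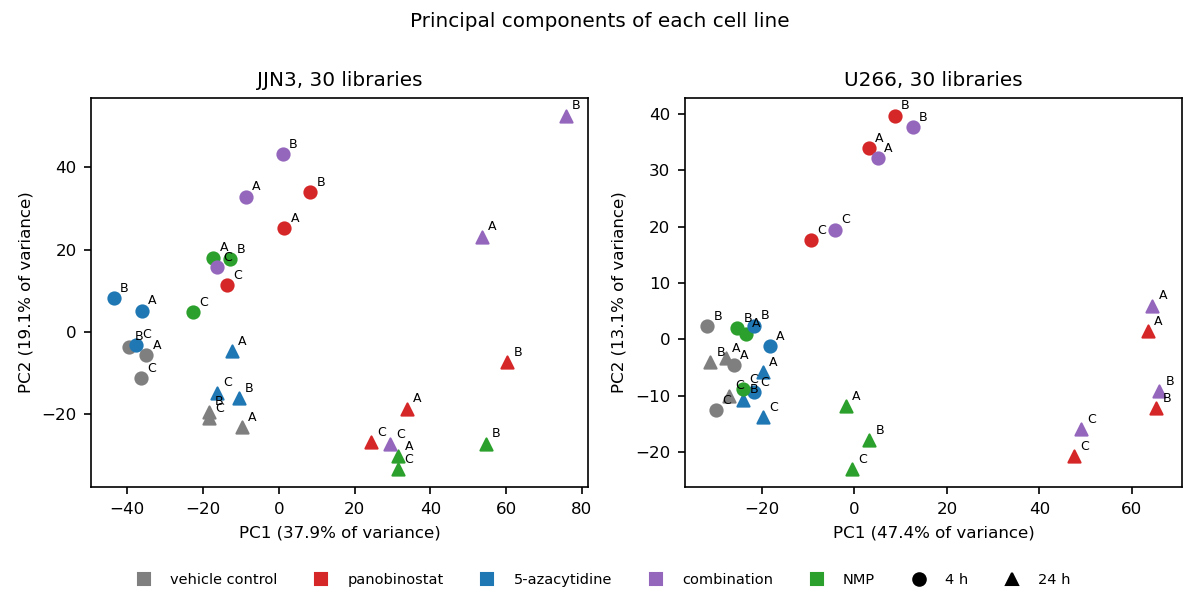
Scores of each library on the first and second principal components of the log2 values within JJN3 and U266, in log2 units. Colours are treatments, circles 4 h, triangles 24 h, and letters replicates; the components held 37.9% and 19.1% of variance in JJN3 and 47.4% and 13.1% in U266.

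**Figure D2:**
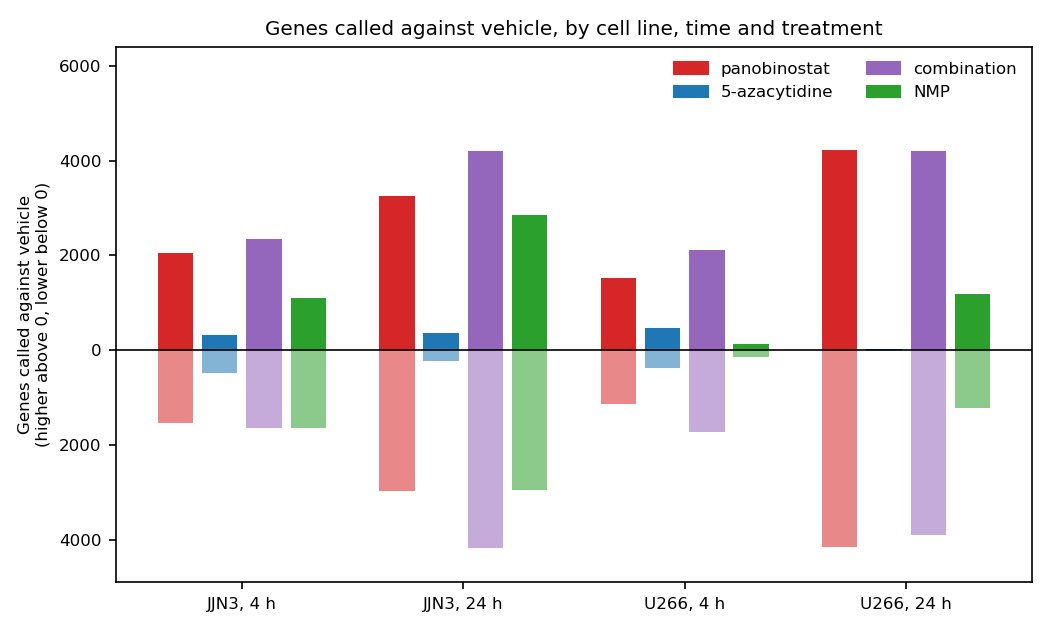
Number of genes called against vehicle for each cell line, time and treatment, with genes called higher above 0 and genes called lower below 0. Bars are counts among 17464 genes, 3 libraries per group.

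After 4 h of panobinostat, the largest rises shared by the lines were in genes with a low level in vehicle. SLC2A4, the insulin-responsive glucose transporter, rose 15.7-fold in JJN3 (log2 change 3.97, SE 0.58, adjusted p = 1.1e-06) and 32.3-fold in U266 (5.01, SE 0.58, adjusted p = 1.0e-08). CCDC184 rose by 4.93 in JJN3 (SE 0.72) and at least 15.6-fold in U266, where vehicle had 0 counts and treated cells 52. CASTOR1, a cytosolic arginine sensor that restrains mTORC1, rose at least 10.8-fold in JJN3 (0 to 30 counts) and by a ratio of 53.1 in U266 (1 to 59 counts; counting interval 9.17 to 2130). The transcription factor EGR2 rose by 3.60 in JJN3 (SE 0.85) and 3.57 in U266 (SE 0.85). The largest falls shared by the lines were ATXN7L2 (-2.77 in JJN3 and -2.36 in U266, SE 0.35), the zinc finger gene PRDM10 (-2.46 and -2.33, SE 0.32), AP5S1 (-2.29 and -2.05, SE 0.24) and NRDE2, a nuclear RNA surveillance factor (-2.24 and -2.03, SE 0.27).

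Among the panel, BMF, which antagonizes pro-survival BCL2 proteins, rose in both lines at 4 h (1.89 in JJN3 and 1.79 in U266, SE 0.22). In JJN3, MYC fell by 0.98 (SE 0.35, adjusted p = 0.037) and CCND2 fell by 1.04 (SE 0.36), while CDKN1A rose by 2.85 (SE 0.64), BCL2L11 by 1.47 (SE 0.28), MCL1 by 0.61 (SE 0.17) and HEXIM1 by 0.64 (SE 0.23). In U266, XBP1, the driver of the secretory program of plasma cells, fell by 1.51 (SE 0.20, adjusted p = 1.2e-07) and CCND1 fell by 1.68 (SE 0.39). There were 3602 genes called in JJN3 (2062 higher and 1540 lower, or 1815 and 1822 with median centring) and 2648 in U266 (1523 and 1125), or 2123 and 1644 without panobinostat replicate B. The lines shared 767 genes called higher, against 179.8 if independent, and 726 called lower, against 99.2.

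Camera called 9 lists in JJN3 at 4 h. Immediate early genes rose in 9 of 18 and fell in 1 (10 and 1 adjusted over the list alone, median 0.99), led by NR4A1 (4.54), NR4A2 (3.76), FOSB (3.56) and JUN (1.45). MYC-driven ribosome biogenesis fell in 12 of 29 (16 adjusted over the list alone, median -0.53), including PPAN (-1.80) and GRWD1 (-1.04). Their adjusted p = 0.443 and 0.414 with an estimated correlation. The p53 pathway targets rose in 8 of 25 with 2 falls (9 and 2 adjusted over the list alone, TP53INP1 2.22). This had adjusted p = 0.155 with an estimated correlation. Type I interferon genes rose in 8 of 38 (8 adjusted over the list alone, median 0.31; OASL 4.70). Neuronal genes rose in 7 of 31 (8 adjusted over the list alone, TUBB3 3.99). For these 2 lists adjusted p = 0.555 and 0.732 with an estimated correlation.

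In U266 at 4 h, camera called 4 lists. Immediate early genes rose in 7 of 18 (9 rose and 1 fell adjusted over the list alone, median 0.85), with FOSB at 3.10 and NR4A1 at 2.88. G2 and mitosis genes fell in 5 of 30 (8 adjusted over the list alone, CENPA -0.91). Integrated stress response genes fell in 5 of 28 (5 adjusted over the list alone, CEBPB -1.57). In this order adjusted p = 0.499, 0.722 and 0.524 with an estimated correlation.

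After 24 h of panobinostat, the largest shared rises started from few counts. AZGP1, a secreted lipid-mobilizing glycoprotein, rose at least 71-fold in JJN3 (0 to 236 counts) and at least 112-fold in U266 (0 to 371). SNCB, beta-synuclein, rose by 6.83 in JJN3 (SE 0.76; 5 to 683 counts) and at least 70.7-fold in U266. PHOSPHO1 rose at least 43.9-fold in JJN3 and by a ratio of 905 in U266 (1 to 1002 counts; 162 to 35800), and IGSF3 by ratios of 99.3 (27.2 to 825) and 177 (60.2 to 859). The glycine transporter SLC6A9 fell by 3.05 in JJN3 and by 3.58 in U266 (SE 0.37). TERT, the telomerase catalytic subunit, fell (-2.72 and -2.09, SE 0.62), as did CARMIL2 (-2.63 and -2.05, SE 0.45) and LRRC14B (-2.55 and -2.05, SE 0.47).

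Plasma cell genes fell at 24 h, most in U266: SDC1, the surface marker CD138, fell by 2.75 (SE 0.21, adjusted p = 4.7e-15), XBP1 by 2.41 (SE 0.20), TNFRSF17 by 2.07 (SE 0.61), IRF4 by 1.38 (SE 0.21), IKZF1 by 1.14 and PRDM1 by 0.87. CCND1, overexpressed in U266 through a rearrangement of its locus, fell by 2.73 (SE 0.39) and CCND2 by 1.25, while MCL1 fell by 0.66 (SE 0.17). CDKN1A rose by 2.26, MAF by 1.66, HEXIM1 by 1.60 (SE 0.23) and BMF by 1.58. In JJN3, SDC1 fell by 1.28 (SE 0.21), CCND2 by 0.97 and DNMT1 by 0.71. CDKN1A rose by 1.95, BMF by 1.27, BCL2L11 by 0.98, MAF by 0.97 and CRBN, the target of lenalidomide, by 0.50 (SE 0.14). CCND1 also rose by 1.26 (SE 0.39) in JJN3, from 51 to 139 counts, a level at which reads carried over from U266 were not excluded. There were 6218 genes called in JJN3 (3247 higher and 2971 lower, or 3016 and 3395 with median centring and 2384 and 554 with a 2-fold minimum; 3836 calls without panobinostat B) and 8374 in U266 (4227 and 4147, or 3653 and 5238 with median centring and 3205 and 1348 with a 2-fold minimum). The lines shared 1817 genes called higher (785.9 if independent) and 2045 called lower (705.5). The median level rose by 0.15 in U266 and 0.11 in the U266 24 h combination, but the median change was -0.008 and 0.015.

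Proliferation and growth lists fell together at 24 h. S phase genes fell in 26 of 29 in JJN3 (28 fell and 1 rose adjusted over the list alone, median -0.96) and 28 in U266 (28 adjusted over the list alone, -1.24), with CDC45 (-1.48) and E2F1 (-1.34) in JJN3. MYC-driven metabolism fell in 28 of 30 in each line (29 and 30 adjusted over the list alone, -0.77 and -0.94) and MYC-driven ribosome biogenesis in 27 of 29 (27 adjusted over the list alone in each; -0.85 and -1.02), and SLC7A5, the leucine transporter, fell by 1.70 in JJN3. In JJN3 adjusted p = 0.261, 0.151 and 0.268 with an estimated correlation. The U266 calls had adjusted p = 0.289, 0.229 and 0.344 with an estimated correlation. G2 and mitosis genes fell in 23 of 30 in U266 (24 adjusted over the list alone, -0.71) and 7 in JJN3 (5 adjusted over the list alone, -0.37), with adjusted p = 0.53 and 0.772 with an estimated correlation.

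Secretory and stress lists fell as well at 24 h. Plasma cell identity fell in 22 of 29 in U266 (23 adjusted over the list alone, median -1.31; ELL2 -1.48), with adjusted p = 0.128 with an estimated correlation. ER chaperones fell in 18 of 25 in U266 (18 adjusted over the list alone, -0.70) and 11 in JJN3 (12 adjusted over the list alone, HYOU1 -1.37), with adjusted p = 0.276 and 0.411 with an estimated correlation. The integrated stress response fell in 16 of 28 in U266 and 18 in JJN3, with 1 rise in each (16 and 19 falls adjusted over the list alone, both medians -0.76), with adjusted p = 0.242 and 0.237 with an estimated correlation. In JJN3 heat shock genes fell in 12 of 23 with 3 rises (14 and 3 adjusted over the list alone, HSPB1 rose by 2.74 and HSPE1 fell by 1.14). Here adjusted p = 0.555 with an estimated correlation.

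Chromatin lists moved in both directions at 24 h. Bromodomain proteins fell in 12 of 28 in JJN3 (12 adjusted over the list alone, KAT2A -1.46) and 11 in U266 with 2 rises (11 and 2 adjusted over the list alone, BRPF3 -1.81), with adjusted p = 0.609 and 0.788 with an estimated correlation. DNA methylation machinery fell in 8 of 14 in JJN3 with 1 rise (8 and 1 adjusted over the list alone, DNMT3B -1.01) and 6 in U266 (6 adjusted over the list alone), with adjusted p = 0.587 and 0.561 with an estimated correlation. In U266, genes commonly raised by BET inhibitors rose in 7 of 10 (7 adjusted over the list alone, SERPINI1 3.60) and polyadenylated and linker histones in 10 of 18 with 1 fall (10 and 1 adjusted over the list alone), with adjusted p = 0.634 and 0.796 with an estimated correlation. Immediate early genes rose in 14 of 18 in U266 with 1 fall (14 and 1 adjusted over the list alone, median 1.66; adjusted p = 0.417 with an estimated correlation).

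Genes of other lineages rose at 24 h. Neuronal genes rose in 17 of 31 in JJN3 (18 adjusted over the list alone, median 2.07; L1CAM 4.39, SYT5 4.02) and 23 in U266 (23 adjusted over the list alone, 2.34; RUNDC3A 5.14, L1CAM 5.07). With adjusted p = 0.267 and 0.264 with an estimated correlation, these calls depend on the preset. Stromal and epithelial markers rose in 5 of 12 in JJN3 with 1 fall (6 and 1 adjusted over the list alone, COL1A1 5.26) and 8 in U266 (9 adjusted over the list alone, KRT18 4.83), with adjusted p = 0.237 and 0.139 with an estimated correlation. Erythroid markers rose in 7 of 8 in JJN3 (7 adjusted over the list alone): HBB at least 13.8-fold, HBG2 by 4.77, HBG1 by 4.37 and HBD by 2.48, with adjusted p = 0.146 with an estimated correlation. Type I interferon genes rose in 17 of 38 in JJN3 with 1 fall (20 and 2 adjusted over the list alone, OAS1 3.28, IFI6 2.89; adjusted p = 0.237 with an estimated correlation).

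With 5-azacytidine alone at 4 h after pre-treatment, the shared changes included ATF4 targets and INSIG1. SLC7A11, the cystine transporter induced by ATF4, rose by 1.89 in JJN3 and 1.47 in U266 (SE 0.36), and INHBE, another target of this response, by 1.74 and 1.95 (SE 0.43). SLC35F1 rose by 2.14 and 2.40 (SE 0.60), and PIP5KL1 by 1.93 in U266 (SE 0.49) and from 2 to 11 counts in JJN3, a ratio of 5.9 (1.29 to 54.8). INSIG1, a sterol-regulated brake on cholesterol synthesis, fell (-2.28 and -1.64, SE 0.38), as did the plasma cell antigen GPRC5D (-2.44 and -1.79, SE 0.53) and SMOC1 (-1.75 and -1.82, SE 0.44). In the panel, HMOX1 rose by 1.94 in U266 (SE 0.59, adjusted p = 0.043), and no other panel gene was called in either line.

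There were 806 genes called in JJN3 at 4 h (330 higher and 476 lower, or 480 and 341 with median centring) and 840 in U266 (467 and 373, or 384 and 479 with median centring). With a replicate block the counts were 1831 and 1810. Leaving out 5-azacytidine A gave 228 in JJN3 and 358 in U266. The lines shared 38 genes called higher (8.8 if independent) and 47 called lower (10.2).

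The integrated stress response rose in 23 of 28 genes in U266 at 4 h (26 adjusted over the list alone, median 1.25, camera adjusted p = 1.38e-39), with TRIB3 at 2.23, ATF5 at 1.72, PCK2 at 1.55 and CEBPG at 0.95, and this call was kept with adjusted p = 0.000142 with an estimated correlation. In JJN3 it rose in 5 of 28 (6 adjusted over the list alone, ATF3 2.03), with adjusted p = 0.411 with an estimated correlation. Cholesterol synthesis fell in 9 of 23 genes in JJN3 (12 adjusted over the list alone, median -0.54, LSS -1.08) and 12 in U266 (18 adjusted over the list alone, -0.66, ACAT2 -1.14), with adjusted p = 0.155 and 0.0567 with an estimated correlation (0.021 in U266 with a replicate block as well).

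Cell cycle lists fell with 5-azacytidine at 4 h in U266: S phase in 17 of 29 (26 adjusted over the list alone, median -0.77, CCNE1 -1.17) and G2 and mitosis in 11 of 30 (17 adjusted over the list alone, PRC1 -0.93). These lists had adjusted p = 0.136 and 0.181 with an estimated correlation. In U266, p53 targets rose in 5 of 25 (7 adjusted over the list alone, SESN2 1.96). These had adjusted p = 0.105 with an estimated correlation. In JJN3, ER chaperones fell in 9 of 25 (12 fell and 1 rose adjusted over the list alone, CRELD2 -0.97). These had adjusted p = 0.237 with an estimated correlation.

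With 5-azacytidine at 24 h, germline genes rose in JJN3. DAZL, a germ cell RNA-binding protein, went from 1 to 341 counts, a ratio of 318 (56.6 to 12600). HORMAD1 rose at least 25.2-fold (0 to 81 counts), RBM46 at least 16.5-fold (0 to 53) and MAGEC1 by 1.98 (SE 0.27). Cancer-testis genes rose in 17 of 34 with 1 fall (21 and 1 adjusted over the list alone, median 1.40, camera adjusted p = 1.88e-23), a call kept with adjusted p = 4.19e-06 with an estimated correlation, while the median in U266 was 0.01. At 4 h the list was called higher in JJN3 with 1 of 34 called (1 adjusted over the list alone, median 0.38), with adjusted p = 0.242 with an estimated correlation. Genes called in both lines in the same direction were ANTXR1, a collagen-binding receptor (3.41 in JJN3, SE 0.60, and at least 6.45-fold in U266, 0 to 20 counts), SELENON (1.12 and 1.13, SE 0.23), the core fucosyltransferase FUT8 (-0.60 and -0.78, SE 0.16) and PCGF3 (-0.42 and -0.44, SE 0.10). No panel gene was called in either line at 24 h.

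There were 575 genes called in JJN3 at 24 h (357 higher and 218 lower) and 47 in U266 (25 and 22; 1217 at unadjusted p under 0.05). A replicate block gave 183 in U266. Leaving out 1 library gave as few as 281 in JJN3 and 14 in U266. The lines shared 2 genes called higher (0.5 if independent) and 2 called lower (0.3). Genes called at both times in the same direction numbered 80 higher (6.7 if independent) and 87 lower (5.9) in JJN3 and 8 higher (0.7) and 8 lower (0.5) in U266.

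Among further lists at 24 h, G2 and mitosis fell in 2 of 30 in U266 (23 adjusted over the list alone, median -0.54, camera adjusted p = 5.17e-27), with adjusted p = 0.0675 with an estimated correlation. ER chaperones fell in 1 of 25 in U266 (5 adjusted over the list alone) and 4 in JJN3 (8 adjusted over the list alone), with adjusted p = 0.139 and 0.148 with an estimated correlation (0.048 and 0.049 with a replicate block as well). HLA class II was called higher in U266 with 0 of 15 called (0 adjusted over the list alone), with adjusted p = 0.661 with an estimated correlation. In JJN3, cholesterol synthesis fell in 2 of 23 (6 adjusted over the list alone) and plasma cell identity in 6 of 29 (8 fell and 1 rose adjusted over the list alone), both with adjusted p = 0.237 with an estimated correlation.

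After 4 h of the combination, the shared rises included CCDC184, CASTOR1 and SMIM10L2B. CCDC184 rose by 4.98 in JJN3 (SE 0.72) and at least 9.24-fold in U266 (0 to 34 counts), and CASTOR1 at least 6.95-fold in JJN3 and by a ratio of 45.7 in U266 (7.87 to 1840). SMIM10L2B rose at least 32.6-fold in JJN3 and by a ratio of 31 in U266 (5.24 to 1260), and the transcription factor CASZ1 by ratios of 29.3 (9.73 to 145) and 23.2 (6.15 to 197). KDM8, a JmjC oxygenase, fell (-2.40 in JJN3 and -2.68 in U266, SE 0.27), as did ATXN7L2 (-2.10 and -2.39, SE 0.35), ZNF628 (-2.08 and -2.21, SE 0.24) and the glycosyltransferase MGAT3 (-2.17 and -2.04, SE 0.49).

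In the panel at 4 h, PRDM1, the master regulator of plasma cells, fell in both lines (-1.08 and -1.10, SE 0.30), while BMF (1.76 and 1.60) and CRBN (0.60 and 0.40) rose. In JJN3, MYC fell by 2.17 (SE 0.35, adjusted p = 6.0e-06), CCND2 by 1.26 and MAF by 1.22, while CDKN1A rose by 2.25, BCL2L11 by 1.60, HEXIM1 by 0.70 and MCL1 by 0.60, and CCND1 rose by 1.53 from 31 to 117 counts. In U266, CCND1 fell by 2.14 (SE 0.39), XBP1 by 1.91 (SE 0.20), DNMT1 by 0.75 and SDC1 by 0.72. There were 4003 genes called in JJN3 (2358 higher and 1645 lower; 2572 without combination B) and 3846 in U266 (2112 and 1734, or 1768 and 2005 with median centring). The lines shared 945 genes called higher (285.2 if independent) and 716 called lower (163.3).

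Immediate early genes rose at 4 h of the combination in 10 of 18 in JJN3 with 2 falls (11 and 2 adjusted over the list alone, FOSB 4.58) and 7 in U266 with 1 fall (9 and 1 adjusted over the list alone, NR4A1 2.94). Plasma cell identity fell in 8 of 29 in JJN3 with 2 rises (12 and 2 adjusted over the list alone, FCRL5 -1.83) and 12 in U266 with 1 rise (12 and 1 adjusted over the list alone, KLF2 -2.63). The p53 targets rose in 11 of 25 in JJN3 with 1 fall (13 and 4 adjusted over the list alone, TP53INP1 1.89) and 8 in U266 with 2 falls (9 and 2 adjusted over the list alone, BBC3 1.69). The JJN3 calls had adjusted p = 0.339, 0.356 and 0.181 with an estimated correlation. The U266 calls had adjusted p = 0.633, 0.186 and 0.237 with an estimated correlation.

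In JJN3 at 4 h, ribosome biogenesis fell in 9 of 29 (9 adjusted over the list alone, PPAN -1.56) and pro-death BCL2 members rose in 5 of 11 with 1 fall (6 and 2 adjusted over the list alone, HRK 3.45). The calls gave adjusted p = 0.61 and 0.237 with an estimated correlation. In U266, G2 and mitosis fell in 23 of 30 (25 adjusted over the list alone, median -0.69, CCNA2 -1.52), S phase in 16 of 29 (21 fell and 1 rose adjusted over the list alone, -0.67, GINS3 -2.01) and cholesterol synthesis in 8 of 23 (9 adjusted over the list alone, ACAT2 -1.19). Genes of the integrated stress response rose in 13 of 28 with 1 fall (18 and 2 adjusted over the list alone, median 0.74, CTH 1.94). In this order adjusted p = 0.231, 0.417, 0.499 and 0.289 with an estimated correlation.

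After 24 h of the combination, IGSF3, CCNA1, PHOSPHO1 and SNCB had the largest shared rises. CCNA1, a germ cell cyclin, rose by a ratio of 681 in JJN3 (1 to 725 counts, 122 to 26900) and at least 227-fold in U266 (0 to 729 counts). IGSF3 rose by ratios of 245 (67.6 to 2030) and 237 (80.9 to 1150), PHOSPHO1 at least 117-fold in JJN3 and by a ratio of 692 in U266 (124 to 27400), and SNCB by 6.54 in JJN3 (SE 0.76) and at least 48.5-fold in U266. SLC6A9 fell 12.2-fold in JJN3 (-3.61, SE 0.37) and 21.6-fold in U266 (-4.43, SE 0.37). Plasma and B lineage genes fell as well: MZB1, a chaperone of antibody secretion (-3.38 and -2.74, SE 0.41), the surrogate light chain gene IGLL1 (-3.45 and -2.90, SE 0.29) and DOK3 (-2.86 and -3.03, SE 0.47).

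In the panel at 24 h, SDC1 (-1.45 in JJN3 and -2.81 in U266, SE 0.21), XBP1 (-1.31 and -2.53, SE 0.20), TNFRSF17 (-2.98 and -1.72), CCND2 (-2.31 and -1.32), IRF4 (-1.01 and -1.18), IKZF1 (-0.83 and -1.09), PRDM1 (-0.91 and -0.89) and DNMT1 (-0.63 and -0.74) fell in both lines. CDKN1A (3.16 and 1.76), BMF (2.03 and 1.26) and HEXIM1 (0.70 and 1.47) rose in both. Without combination B the JJN3 changes of IKZF1 (0.01, adjusted p = 0.98), PRDM1 (-0.16, adjusted p = 0.61) and HEXIM1 (0.22, adjusted p = 0.42) were not called. MCL1, a survival protein of myeloma cells, rose by 0.78 in JJN3 and fell by 0.72 in U266 (SE 0.17). In JJN3 alone MYC fell by 1.86 (SE 0.35), and HMOX1 rose by 3.10 (SE 0.59), BCL2L11 by 1.28 and CRBN by 0.36. CRBN and DNMT1 lost their JJN3 calls when any single vehicle library was left out, and with only the libraries compared the JJN3 calls kept were those of SDC1, XBP1, CCND2, BMF and BCL2L11. In U266 alone CCND1 fell by 2.78 and IKZF3 by 1.93, and MAF rose by 1.48. There were 8366 genes called in JJN3 (4195 higher and 4171 lower, or 2950 and 1560 with a 2-fold minimum; 3149 with only the libraries compared) and 8096 in U266 (4201 and 3895, or 3712 and 4732 with median centring and 3135 and 1486 with a 2-fold minimum). The lines shared 2214 genes called higher (1009.1 if independent) and 2216 called lower (930.3).

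Cancer-testis genes rose at 24 h of the combination in 25 of 34 in JJN3 with 1 fall (25 and 1 adjusted over the list alone, median 2.13, GTSF1 3.26), with DAZL from 1 to 339 counts, a call kept with adjusted p = 0.0115 with an estimated correlation. Neuronal genes rose in 26 of 31 in JJN3 with 2 falls (27 and 2 adjusted over the list alone, median 3.61, KIF1A 7.14), and in 25 in U266 (25 adjusted over the list alone, 2.27, RUNDC3A 4.89). Stromal and epithelial markers rose in 9 of 12 in JJN3 with 1 fall (10 and 1 adjusted over the list alone, COL1A1 5.91) and 8 in U266 (8 adjusted over the list alone, KRT18 4.83). Immediate early genes rose in 14 of 18 in JJN3 with 1 fall (14 and 2 adjusted over the list alone, IER3 3.64) and 12 in U266 (12 adjusted over the list alone, NR4A2 4.12). For these 3 lists adjusted p = 0.151, 0.133 and 0.53 in JJN3 and 0.261, 0.146 and 0.53 in U266 with an estimated correlation.

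Growth lists fell at 24 h of the combination. Ribosome biogenesis fell in 29 of 29 in JJN3 (29 adjusted over the list alone, median -1.10, NOP16 -2.08) and 26 in U266 (26 adjusted over the list alone, LYAR -1.88). MYC-driven metabolism fell in 25 of 30 in JJN3 with 2 rises (26 and 2 adjusted over the list alone, HSPE1 -1.61) and 21 in U266 (24 adjusted over the list alone, SLC7A5 -2.12). S phase fell in 28 of 29 in U266 (28 adjusted over the list alone, -1.49, CDC45 -2.37) and 16 in JJN3 (17 adjusted over the list alone, TYMS -2.55). G2 and mitosis fell in 25 of 30 in U266 (25 adjusted over the list alone, CCNA2 -2.17) and 12 in JJN3 with 1 rise (12 and 1 adjusted over the list alone, KIF20A -1.17). The JJN3 calls had adjusted p = 0.237, 0.237, 0.737 and 0.791 with an estimated correlation. In U266 adjusted p = 0.482, 0.266, 0.237 and 0.237 with an estimated correlation.

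Secretory lists fell too. Plasma cell identity fell in 21 of 29 in JJN3 with 2 rises (23 and 2 adjusted over the list alone, SLAMF7 -2.53) and 23 in U266 (24 adjusted over the list alone, ELL2 -1.47). ER chaperones fell in 12 of 25 in JJN3 (12 adjusted over the list alone, PDIA3 -1.05) and 17 in U266 (18 adjusted over the list alone, HSPA5 -1.91). The integrated stress response fell in 13 of 28 in JJN3 with 4 rises (13 and 4 adjusted over the list alone, CBS -1.85) and 20 in U266 (21 adjusted over the list alone, PHGDH -1.78). Cholesterol synthesis fell in 12 of 23 in JJN3 (12 adjusted over the list alone, ACAT2 -1.21) and 10 in U266 (10 adjusted over the list alone, ACAT2 -1.39). DNA methylation machinery fell in 10 of 14 in JJN3 (10 adjusted over the list alone, ZBTB38 -1.65) and 8 in U266 (9 fell and 1 rose adjusted over the list alone, MBD4 -1.16). In JJN3 adjusted p = 0.231, 0.498, 0.722, 0.602 and 0.44 with an estimated correlation. The U266 calls had adjusted p = 0.099, 0.266, 0.181, 0.677 and 0.524 with an estimated correlation.

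Further lists were called in JJN3 alone at 24 h of the combination. Interferon genes rose in 23 of 38 with 3 falls (23 and 3 adjusted over the list alone, OASL 5.80). Oxidative stress genes rose in 14 of 19 with 2 falls (15 and 2 adjusted over the list alone). For these adjusted p = 0.229 and 0.63 with an estimated correlation. HLA class I fell in 10 of 16 with 1 rise (10 and 1 adjusted over the list alone, PSMB10 -2.24) and myeloid markers rose in 4 of 5 (4 adjusted over the list alone). Here adjusted p = 0.592 and 0.151 with an estimated correlation.

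Against panobinostat alone at 24 h, SFN, the p53-inducible 14-3-3 sigma, was higher with the combination in JJN3 (1 to 234 counts), as were PNMA5 (6.40, SE 0.70, 5 to 350 counts) and NEFH (0 to 158 counts), while HBB (46 to 2 counts), TMPRSS15 (-3.64, SE 0.61) and POU2F3 (-3.55, SE 0.71) were lower. Called genes numbered 2717 (1378 higher and 1339 lower, or 1898 and 960 with median centring), 4491 with a replicate block and 0 with only the libraries compared. Leaving out panobinostat A or C or combination B or C gave 1533, 1650, 679 or 5809. Cancer-testis genes were higher in 18 of 34 (median 1.25), histones in 10 of 18 (1.00) and oxidative stress genes in 9 of 19 (0.92), and plasma cell identity was lower in 19 of 29 with 1 higher (-0.83). In U266 there were 7 calls (2 higher and 5 lower, or 3 and 2 with median centring and 21 and 14 with quantile normalization), 37 with a replicate block and 0 with a stricter filter. Leaving out panobinostat A or C or combination A, B or C gave 4, 0, 0, 1 or 18. MAEL, a germline transposon silencer, was higher by 4.11 (SE 0.73, 22 to 401 counts) and HACD1 went from 1 to 8 counts. NAPRT (20 to 3 counts), the apoptosis inhibitor BIRC5 (-0.84, SE 0.17) and the cell cycle kinase subunit CKS1B (-0.75, SE 0.15) were lower.

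At 4 h the combination differed from panobinostat in 802 genes in JJN3 (435 higher and 367 lower; 1717 with a replicate block) and 236 in U266 (153 and 83, or 131 and 125 with median centring; 739 with a replicate block). Leaving out panobinostat A or B or combination A gave 330, 316 or 167 in JJN3 and 97, 143 or 101 in U266. GREB1L (2 to 67 counts), FMR1NB (3 to 46) and BCL6B (1 to 24) were higher in JJN3, and the receptor subunit CHRNA1 (16 to 0 counts), SORBS2 (-2.84, SE 0.51) and cytidine deaminase CDA (13 to 0 counts) lower. In U266, S100P (3.38, SE 0.60), KLHDC7B (3.35, SE 0.73) and the retinol-processing gene DHRS3 (3.34, SE 0.62) were higher, and IL36A (16 to 1 counts), ZNF365 (-2.32, SE 0.48) and ADGRA3 (-1.99, SE 0.54) lower. The integrated stress response was higher in 16 of 28 genes in U266 (median 1.03) and 5 in JJN3. The non-additive effect had 106 calls in JJN3 at 24 h (52 higher and 54 lower, or 68 and 40 with median centring), 3 with only the 30 libraries of the line and 0 with only the libraries compared. In the fit of all libraries PRR20G (109 counts in the combination against 0 in vehicle, panobinostat and 5-azacytidine), PRKCZ (51 against 3, 2 and 2) and DNAH3 (52 against 11, 8 and 1) exceeded the sum, and HBB (2 against 0, 46 and 2), CXCL13 (-4.19, SE 1.03) and SOX9 (-4.13, SE 0.92) fell short of it. Leaving out combination B or C gave 20 or 2329. Limma called 0 genes at 4 h in JJN3 (449 at unadjusted p under 0.05; quantile normalization 1) and in U266 (1.53% of genes at that level, replicate block 1), and 1 in U266 at 24 h (430; replicate block 3, stricter filter 0).

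NMP at 4 h removed most MYC transcript from JJN3. MYC fell 29.3-fold there (-4.88, SE 0.35, adjusted p = 1.4e-14, 79339 to 2707 counts), and in U266, with 359 vehicle counts, its change of -1.14 (SE 0.35) was not called. HEXIM1, an inhibitor of P-TEFb that rises when BET proteins are displaced, rose in both lines (1.31 and 1.49, SE 0.23), as did RRAD (2.65 and 2.74, SE 0.47), LFNG (3.04 and 2.62, SE 0.73), SERTAD1 (3.65 and 2.46, SE 0.41) and the Wnt receptor FZD7 (3.37 and 2.43, SE 0.42). The chemokine receptors CCR2 (-3.49 and -3.39, SE 0.64) and CCR1 (-2.96 and -2.63, SE 0.42), the Wnt antagonist DKK1 (-2.13 and -4.62, SE 0.61) and DEPP1 (-1.95 and -2.55, SE 0.29) fell. IRF4 (-1.07 and -1.13, SE 0.21), PRDM1 (-1.61 and -1.33, SE 0.30) and BMF (-0.84 and -1.16, SE 0.22) fell in both lines. In JJN3 MAF fell by 2.10, SDC1 by 1.39, CCND2 by 1.08 and IKZF1 by 0.85, and CDKN1A rose by 2.53, BCL2L11 by 0.79 and MCL1 by 0.55. In U266 XBP1 fell by 0.93.

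There were 2742 genes called in JJN3 at 4 h of NMP (1104 higher and 1638 lower, or 1380 and 1303 with median centring; 1719 without NMP B) and 275 in U266 (136 and 139; 664 with a replicate block). Leaving out NMP C gave 156 in U266. The lines shared 75 genes called higher (8.6 if independent) and 85 called lower (13).

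Genes commonly raised by BET inhibitors rose at 4 h of NMP in 7 of 10 in JJN3 (8 adjusted over the list alone, median 2.26, H2BC5 3.81) and 2 in U266 (7 adjusted over the list alone, 1.00, BRD2 1.38), with adjusted p = 0.0533 and 0.115 with an estimated correlation (0.016 and 0.04 with a replicate block as well). NF-kappaB targets fell in 8 of 25 in JJN3 (9 fell and 1 rose adjusted over the list alone, median -0.54, TNFAIP3 -1.45), a call kept with adjusted p = 0.0417 with an estimated correlation, and in 4 in U266 (4 adjusted over the list alone, IL6 -3.44), with adjusted p = 0.0533 with an estimated correlation (0.012 with a replicate block as well). Histones rose in 11 of 18 in JJN3 (12 adjusted over the list alone, H2BC11 3.36) and 0 in U266 (7 adjusted over the list alone, median 0.66), and plasma cell identity fell in 8 of 29 in JJN3 with 1 rise (12 and 1 adjusted over the list alone, PIM2 -1.02) and 6 in U266 (9 adjusted over the list alone, PIM2 -0.83). The JJN3 calls had adjusted p = 0.148 and 0.401 with an estimated correlation. In U266 adjusted p = 0.417 and 0.108 with an estimated correlation.

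In JJN3 at 4 h of NMP, ribosome biogenesis fell in 19 of 29 (20 adjusted over the list alone, RRS1 -1.88) and G2 and mitosis rose in 6 of 30 with 1 fall (6 and 1 adjusted over the list alone). Here adjusted p = 0.181 and 0.766 with an estimated correlation. In U266, pro-survival BCL2 members were called lower as a list with 0 of 4 called (1 adjusted over the list alone, median -0.51). This had adjusted p = 0.0638 with an estimated correlation (0.049 with a replicate block as well).

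**Figure D3:**
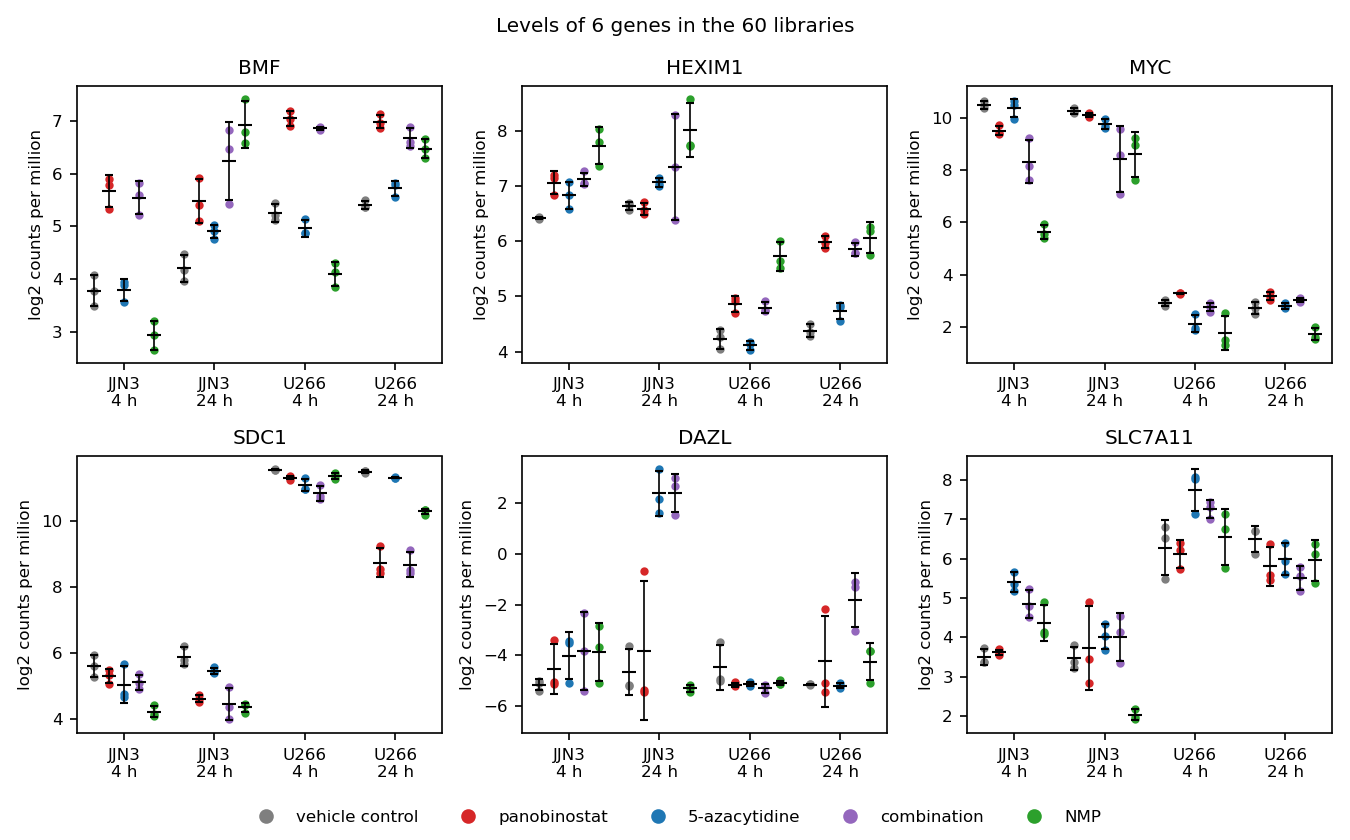
Levels of 6 genes in the 60 libraries in log2 CPM, by cell line, time and treatment. Points are libraries and bars are the mean and SD of 3; DAZL values near the bottom are libraries with 0 counts.

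After 24 h of NMP, MYC was lower by 3.17-fold in JJN3 and 2-fold in U266 (SE 0.35 log2 units), the U266 call being lost with any 1 library left out (adjusted p = 0.061 to 0.17), and HEXIM1 higher (1.38 and 1.68, SE 0.23). RTL5 (3.87 and 3.39, SE 0.53), the receptor tyrosine kinase FGFR3 (3.55 and 3.36, SE 0.70) and periplakin PPL (6.97-fold and 8-fold, SE 0.88 log2 units) rose, as did CAPN5, by a ratio of 33.8 in JJN3 (9.02 to 284) and by 2.97 in U266 (SE 0.89). CCR2 (-3.64 and -3.30, SE 0.64), MZB1 (-2.96 and -2.88, SE 0.41) and the cytokine receptor subunit CSF2RB (-3.10 and -2.73, SE 0.62) fell. ANKRD55 fell by 3.92 in JJN3 (SE 0.66) and from 33 to 3 counts in U266, a ratio of 0.0812 (0.0159 to 0.259). SDC1 (-1.54 and -1.20) and IRF4 (-0.60 and -1.57) fell and BMF (2.73 and 1.06) rose in both lines. In JJN3 CDKN1A rose by 2.98, HMOX1 by 1.94, BCL2L11 by 1.55, MCL1 by 1.32 and CRBN by 0.56, and TNFRSF17 fell by 2.30 and DNMT1 by 0.68. In U266 XBP1 fell by 2.28 (SE 0.20), CCND1 by 1.56 and PRDM1 by 0.91. There were 5796 genes called in JJN3 (2855 higher and 2941 lower) and 2387 in U266 (1177 and 1210, or 873 and 1549 with median centring; 3684 with a replicate block). Leaving out 1 library gave as few as 1460 in U266. The lines shared 632 genes called higher (192.4 if independent) and 822 called lower (203.8).

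Plasma cell identity fell at 24 h of NMP in 19 of 29 in U266 (21 adjusted over the list alone, median -1.11, ELL2 -1.25) and ER chaperones in 19 of 25 (19 adjusted over the list alone, -0.85, SDF2L1 -1.62), calls kept with adjusted p = 0.00187 and 0.0192 with an estimated correlation. In JJN3 they fell in 11 of 29 with 3 rises (11 and 3 adjusted over the list alone, SLAMF7 -2.51) and 15 of 25 (15 adjusted over the list alone, HSP90B1 -1.71), with adjusted p = 0.53 and 0.289 with an estimated correlation. S phase fell in 28 of 29 in JJN3 (29 adjusted over the list alone, median -1.75, CDC45 -2.60) and 23 in U266 (23 adjusted over the list alone, -0.96, MCM10 -1.68). MYC-driven metabolism fell in 26 of 30 in JJN3 (27 adjusted over the list alone, PYCR1 -2.62) and 18 in U266 (20 adjusted over the list alone, PYCR1 -1.56). Ribosome biogenesis fell in 29 of 29 in JJN3 (29 adjusted over the list alone, LYAR -1.93) and 17 in U266 (21 adjusted over the list alone, LYAR -1.52). In JJN3 adjusted p = 0.105, 0.0606 and 0.151 with an estimated correlation. The U266 calls had adjusted p = 0.146, 0.155 and 0.261 with an estimated correlation.

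The integrated stress response fell at 24 h of NMP in 17 of 28 in JJN3 with 2 rises (18 and 2 adjusted over the list alone, SLC6A9 -3.26) and 11 in U266 (13 adjusted over the list alone, STC2 -1.73). G2 and mitosis fell in 15 of 30 in JJN3 (16 adjusted over the list alone, AURKB -1.04). BET-raised genes rose in 8 of 10 in JJN3 (10 adjusted over the list alone, H2BC21 4.05) and 5 in U266 (8 adjusted over the list alone, H2AC6 2.28), and histones in 12 of 18 in JJN3 with 1 fall (12 and 1 adjusted over the list alone) and 4 in U266 with 1 fall (9 and 1 adjusted over the list alone). The JJN3 calls, with G2 and mitosis second, had adjusted p = 0.148, 0.609, 0.232 and 0.472 with an estimated correlation. The U266 calls had adjusted p = 0.181, 0.237 and 0.61 with an estimated correlation.

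Other lists were called in 1 line at 24 h of NMP. In JJN3, heat shock genes fell in 13 of 23 with 1 rise (13 and 1 adjusted over the list alone) and pyrimidine handling in 9 of 19 (9 adjusted over the list alone). CDK inhibitors rose in 5 of 7 (5 adjusted over the list alone, CDKN1C 3.85). The calls gave adjusted p = 0.367, 0.226 and 0.146 with an estimated correlation. In U266, histone deacetylases rose in 1 of 15 (3 adjusted over the list alone) and HLA class II fell in 1 of 15 (1 adjusted over the list alone). For these adjusted p = 0.151 and 0.744 with an estimated correlation.

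**Figure D4:**
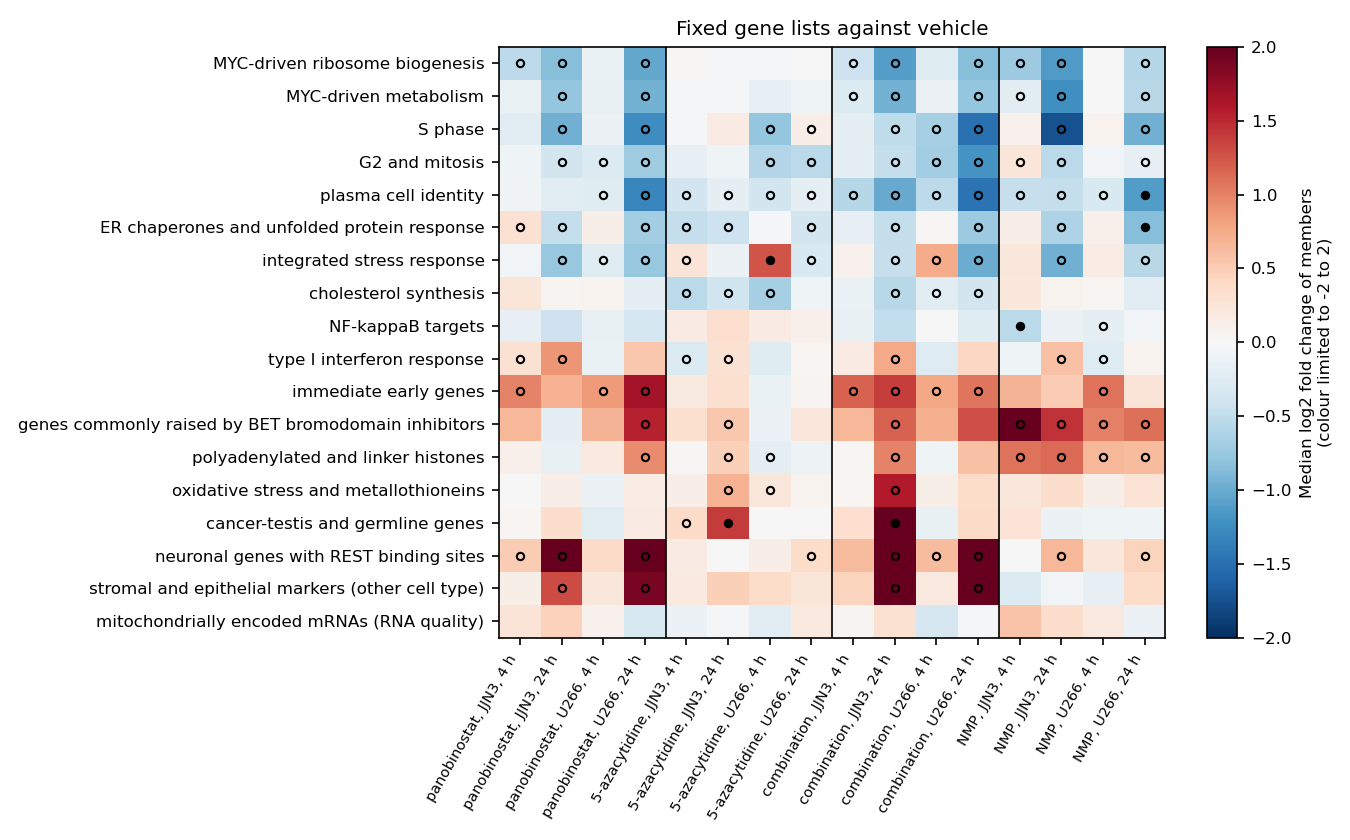
Median log2 change of 18 gene lists in the 16 comparisons with vehicle, 3 libraries per group, colours limited to -2 to 2. Open circles are camera calls with the preset correlation and filled circles those kept with an estimated correlation.

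Over the 528 list tests, camera called 169 and 6 of these calls were kept with an estimated correlation: cancer-testis genes in JJN3 at 24 h of 5-azacytidine and of the combination, the integrated stress response in U266 at 4 h of 5-azacytidine, NF-kappaB targets in JJN3 at 4 h of NMP, and ER chaperones and plasma cell identity in U266 at 24 h of NMP. Lists with 0 calls in the 16 comparisons were mature B cell markers (10 genes, lowest adjusted p = 0.0727 in U266 at 24 h of panobinostat), T and NK cell markers (10 genes, 0.108 in the same comparison) and mitochondrially encoded mRNAs (13 genes, 0.0813 in JJN3 at 4 h of NMP). With an estimated correlation these adjusted p = 0.25, 0.44 and 0.867.

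Between the lines at 4 h, the panobinostat effect differed in 280 genes (121 higher and 159 lower in U266 than in JJN3). ARRDC2, a regulator of receptor endocytosis, went from 3 to 27 counts in U266 and from 1637 to 628 in JJN3 and SLITRK3 from 0 to 47 in U266 with 0 in JJN3. NXPH3 (2 to 128 counts), the protocadherin PCDH17 (7 to 261) and the Notch ligand DLL1 (0 to 79) rose in JJN3 and had 0 or 1 count in treated U266. Leaving out JJN3 vehicle A gave 184 calls, JJN3 panobinostat A, B or C 126, 97 or 500, and U266 panobinostat A or B 152 or 164, and a replicate block gave 830.

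The 5-azacytidine effect at 4 h differed in 241 genes (183 higher and 58 lower, or 138 and 134 with median centring; 876 with a replicate block). KLHDC7B rose in U266 (4 to 165 counts, against 3 to 1 in JJN3), as did SPAG6 (2 to 20), with GRB10 higher there (10 to 51, not called in U266 itself), and GREB1L (0 to 42), SGCE (2 to 29), an imprinted gene, and FMR1NB (1 to 26) rose in JJN3. The integrated stress response was higher in U266 in 8 of 28 genes (median difference 0.97). Leaving out U266 5-azacytidine A gave 101. The combination effect differed in 759 genes (389 and 370; 1899 with a replicate block), led by KLHDC7B, ADAMTS15 and KLHL31 in U266 and GREB1L, PCDH17 and NXPH3 in JJN3, and G2 and mitosis genes were lower in U266 in 8 of 30 (-0.75). CCND1 rose in JJN3 and fell in U266, a difference of -3.67. Leaving out JJN3 combination A, B or C gave 397, 417 or 1166.

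The NMP effect at 4 h differed in 409 genes (303 and 106, or 244 and 139 with median centring; 1056 with a replicate block). The difference was 3.74 for MYC (SE 0.49, adjusted p = 5.7e-06) and 3.70 for PLD6 (SE 0.53), a mitochondrial phospholipase that fell in JJN3 and was not called in U266, and FJX1 fell from 381 to 14 counts in JJN3 with 2 and 3 in U266. TG (3 to 60 counts), GCNT3 (0 to 7) and the adenylate cyclase ADCY5 (6 to 55) rose in JJN3. Ribosome biogenesis genes were higher in U266 in 11 of 29 (0.71). Leaving out JJN3 NMP B or C gave 216 or 647.

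At 24 h the panobinostat effect differed in 3211 genes (1823 higher and 1388 lower in U266, or 1582 and 1773 with median centring). MAOA, the monoamine oxidase (5 to 534 counts), SLITRK3 (0 to 289) and GLT1D1 (0 to 100) rose in U266 and not in JJN3, and HBB (0 to 46), ADD2 (3 to 210) and TSPAN7 (6 to 163) rose in JJN3, while HBB and TSPAN7 fell in U266. CCND1 differed by -3.99. Plasma cell identity was lower in U266 in 17 of 29 genes (median -1.13). The combination effect differed in 4174 genes (2225 and 1949, or 1761 and 2701 with median centring; 2263 with only the libraries compared): GLT1D1, FBP1 (39 to 178 counts, against 401 to 41 in JJN3) and MAOA were higher in U266, and BASP1 (0 to 1559 counts in JJN3), PIMREG (4 to 275) and the cation channel TRPM4 (0 to 816) higher in JJN3. S phase was lower in U266 in 20 of 29 with 1 higher (-0.89) and G2 and mitosis in 18 of 30 (-0.79).

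The 5-azacytidine effect at 24 h differed in 104 genes (44 and 60), with 8 of 34 cancer-testis genes lower in U266 (median -1.28). DAZL, HDGFL1 (0 to 69 counts) and BASP1 (0 to 246) rose in JJN3, and MDFI (3 to 13 counts), CASKIN1 (2 to 11) and PPP4R4 (2 to 18) were higher in U266. Leaving out JJN3 5-azacytidine A gave 53 calls. The NMP effect differed in 1280 genes (694 and 586): WNT8B (91 to 11 counts in JJN3, 1 to 10 in U266), SH2D5 (45 to 1 in JJN3) and CAMKV (219 to 18 in JJN3) were higher in U266, and the sialyltransferase ST6GALNAC2 (-5.64, SE 0.61, 31 to 759 counts in JJN3), CLSTN2 (2 to 77 in JJN3) and FAM153A (53 to 5 in U266) lower. Leaving out JJN3 NMP B gave 597 calls and JJN3 vehicle C 843.

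From 4 h to 24 h, panobinostat effects changed in 4542 genes in U266 (2421 and 2121, or 2104 and 2974 with median centring) and 2131 in JJN3 (1072 and 1059). In U266 the melanosomal receptor GPR143 (2 to 692 counts at 24 h), NLRP5 (0 to 1688) and CCNA1 (0 to 1271) rose late, and ARHGAP9 fell from 1171 to 9 counts at 24 h and not at 4 h (-6.69, SE 0.64), with IGLL5 (-3.92, SE 0.88) and WDR64 (-3.58, SE 0.80). In JJN3 RARRES2 (2 to 105 counts at 24 h), PCDHB6 (1 to 55) and AZGP1 rose late, and SMIM10L2B, SFN and PASD1 rose at 4 h. The 4 h and 24 h calls shared 822 higher (368.6 if independent) and 710 lower genes (267.1) in U266 and 996 (383.4) and 756 (262) in JJN3. S phase declined between the times in 24 of 29 genes in U266 (median -1.06).

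With NMP, effects changed in 2622 genes in JJN3 (1394 and 1228, or 993 and 1678 with median centring) and 426 in U266 (209 and 217, or 178 and 347 with median centring; 1197 with a replicate block). The glutathione-degrading CHAC1 rose at 4 h and fell at 24 h in JJN3 (difference -4.95, SE 0.84), with negative differences also for SH2D5 and ALDH8A1 (-3.87, SE 0.82), while GRHL3 (5.10, SE 0.84), RARRES2 (2 to 28 counts at 24 h) and GPC5 (0 to 30) rose late. S phase declined in 28 of 29 genes (median -1.78) and the integrated stress response in 16 of 28 with 1 rise (-1.35). In U266 DKK1 fell at 4 h alone (difference 4.00, SE 0.86), with ARHGEF40 (4.02, SE 0.75) and DAPK2 (3 to 14 counts at 24 h) higher late and FOSL1 (8 to 1 counts), CD300LF (-3.94, SE 0.79) and KLHDC7B (10 to 1) lower late. Leaving out 1 library gave as few as 209 in U266.

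The combination effect changed between the times in 3834 genes in U266 (2102 and 1732, or 1946 and 2002 with median centring) and 2875 in JJN3 (1443 and 1432, or 1623 and 1036 with median centring; 4859 without the 24 h combination C and 476 with only the libraries compared). In U266 PTGES (0 to 155 counts at 24 h), GPR143 and SLC8A2 (0 to 164) rose late, and ARHGAP9 (-7.56, SE 0.64), KLHDC7B (10 to 0) and SLC6A9 (-5.39, SE 0.52) fell late. In JJN3 HDGFL1 (0 to 207), NEFH and TRPM4 rose late, and FBP1 (-3.72, SE 1.11), SLC6A9 (-3.42, SE 0.52) and MYL2 fell, the last with at most 4 counts. Cancer-testis genes gained in 16 of 34 in JJN3 (median 1.83) and the integrated stress response declined in 20 of 28 in U266 (-1.83). The 5-azacytidine effect changed in 23 genes in JJN3 (22 and 1; 0 with a stricter filter), led by HDGFL1, PNMA5 (1 to 229 counts at 24 h) and DAZL, with TMEM273 lower, and in 73 in U266 (17 and 56; 282 with a replicate block). In U266 KLHDC7B, the transcription factor HNF4A and SPAG6 were raised at 4 h alone, and ARHGAP24, PAQR7 and TNFRSF11A had higher effects late. Leaving out 1 library gave as few as 23 in U266.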

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

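The regroupings of libraries, the test of whether a library had missed panobinostat and the test of carried-over reads as the whole MYC signal of U266 were tests chosen only after the results were seen. Differences between lines or times were called in 280, 241, 759 and 409 genes at 4 h (panobinostat, 5-azacytidine, combination, NMP, U266 minus JJN3), 3211, 104, 4174 and 1280 at 24 h, and from 4 h to 24 h in 2131, 23, 2875 and 2622 genes in JJN3 and 4542, 73, 3834 and 426 in U266. Among named regulators, the lines differed in CCND1 (-3.67 for the 4 h combination and -3.99 for 24 h panobinostat), MCL1 (-1.5 for the 24 h combination) and MYC (3.74 for 4 h of NMP). CCND1 stood in untreated JJN3 at 0.0462% (4 h) and 0.0747% (24 h) of its U266 level, rank 2 from the lowest of 705 and 713 abundant U266 genes and near IGLC2 (0.0591% and 0.0943%). Reads carried over from U266 were not excluded there, and the CCND1 differences depend on it.

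Along each group's own effect, replicate C had the smallest and B the largest response in 8 of 8 panobinostat and combination groups. Mean slopes were 0.90, 1.21 and 0.67 for panobinostat A, B and C, and 0.92, 1.17 and 0.62 for the combination. A general difference of replicate C predicts the same under NMP, where C was smallest in 1 of 4 groups, and lower depth predicts the lowest totals in C, found in 1 of 8. Replicate B was largest under NMP in 3 of 4 groups, so a general difference of replicate B remains open. On the panobinostat effect, a JJN3 24 h combination C without that drug would lie near the 5-azacytidine libraries (0.06 to 0.15). Its slope was 0.65. These results leave the smaller response of replicate C open, which could come from a lower effective dose. That was not tested, since the labels give no dose per replicate.

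MYC fell by 4.88 in JJN3 (95% interval -5.57 to -4.18) and by 1.14 in U266 (-1.83 to -0.44) after 4 h of NMP, a difference of 3.74 (2.75 to 4.72), with untreated U266 at 0.508% of the JJN3 level. A floor predicts U266 counts near the limit of detection, and they lay 6.9 log2 units above 3 counts. Reads carried over from JJN3 predict that no abundant JJN3 gene has a much lower share than MYC: 0 of 788 lay below 0.1 of its share, so carryover of that size remains possible, while 8 lay below 0.5 of it (lowest SLC38A5, 0.0617%), so carryover was not the whole signal. Scaling predicts a difference near 0 with another method, and the lowest was 3.66.

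Cancer-testis and germline genes had a median change of 1.40 in JJN3 and 0.01 in U266 after 24 h of 5-azacytidine. A general rise of low-level genes predicts a similar median in lists matched on level, and the list lay at percentile 100 of 10000 such lists (random median 0.16). A higher starting level in U266 predicts no difference among members low in both lines, and these 13 differed by 2.22 (2.68 in JJN3 and 0.45 in U266). The level filter favors low members that rose somewhere, and without it 16 such members had 2.90 and 0.45. Members absent from the deposited file could not be included. Reads shared between gene copies predict a weaker effect outside gene families, where the median was 1.46 times that of the list. Loss of DNA methylation at these promoters in JJN3 remains possible, and methylation was not measured.

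With 3 libraries against 3, only 10 regroupings exist, too few for a share under 0.05. The real grouping of each treatment against vehicle gave the most calls (1 of 10 as large in every case). The highest other count was 37, 26, 21 and 2 in JJN3 at 4 h (real 3602, 806, 4003 and 2742), 10, 3, 4316 and 2 in JJN3 at 24 h (6218, 575, 8366 and 5796), 24, 12, 7 and 17 in U266 at 4 h (2648, 840, 3846 and 275) and 4, 6, 5 and 2 in U266 at 24 h (8374, 47, 8096 and 2387). The 4316 calls came with combination A and B and vehicle A on one side. For the combination against panobinostat, 1 of 10 reached the real count in JJN3 at 4 h (802, highest other 657) and in U266 at 4 h (236 and 47), 2 of 10 in JJN3 at 24 h (2717 and 5568) and 5 of 10 in U266 at 24 h (7 and 189). The 5568 calls came with combination A and B and panobinostat B on one side, and more calls than the real grouping point to a structure of the samples. Among splits that part all 3 replicate pairs the highest were 7, 1333 and 0 in JJN3 at 4 h and 24 h and U266 at 24 h. For the list tests 1 of 10 was as large (169 and 145).

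For differences of effects, 100 regroupings were used. Those exchanging arms within 1 line or time, or mixing treatments, add their effects, so counts several times the real ones point to sample structure. The real count was reached in 35 and 36 of 100 for the 24 h non-additive effects (JJN3, U266, highest other 9047 and 7845). A real 0, as at 4 h, is always reached, so these decide nothing. The line differences had 11, 3, 12 and 11 at 4 h (highest other 2673, 629, 3044 and 1745) and 10, 3, 12 and 9 at 24 h (7310, 118, 8598 and 4206). The time differences had 7, 17, 13 and 7 in JJN3 (3830, 1879, 8669 and 6088) and 9, 6, 12 and 7 in U266 (8056, 323, 6809 and 1522). Of all 100, a share under 0.05 was reached only by the line differences of 5-azacytidine at 4 h and 24 h. Among regroupings that kept most arms, the real one included, line differences had as many calls in 1 of 49 (5-azacytidine) to 6 of 51 (NMP) at 4 h and 1 of 50 to 5 of 52 at 24 h, and time differences in 1 of 48 (NMP) to 8 of 51 (5-azacytidine) in JJN3 and 2 of 57 to 7 of 53 in U266, so exchanged arms did not account for every large count.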

How the results depend on the processing

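Fits with voom, fits of only the libraries compared, fits of replicates A and B only and list tests with both a replicate block and an estimated correlation were tests chosen only after the results were seen. The planned count tool and pseudocounts 0.1 and 1 were not run. The cause of the shifts below was not tested. For the 1081 pairs of a named gene and a comparison (871 called), leaving out 1 library at a time gave 7086 values: 6541 kept their direction and side of the threshold, 531 lost the call, 13 gained it and 1 reversed, IKZF1 in the JJN3 24 h combination (0.01 without combination B, adjusted p = 0.98, range -1.34 to 0.01). MYC in U266 with NMP at 24 h, MYC in JJN3 with panobinostat at 4 h and HMOX1 in U266 with 5-azacytidine at 4 h lost their calls with most single libraries left out. Low depth limits genes with few counts, whose folds are bounds or intervals. Counts that moved by over 1.5 times follow, and the other counts stayed within it. A 2-fold minimum left, against vehicle (panobinostat, 5-azacytidine, combination, NMP), 1701, 259, 1721 and 1216 in JJN3 at 4 h, 2938, 301, 4510 and 2600 at 24 h, 1004, 310, 1409 and 159 in U266 at 4 h and 4553, 27, 4621 and 921 at 24 h. It left 225, 1199 and 90 for the combination against panobinostat (JJN3 4 h, JJN3 24 h, U266 4 h), 470 and 802 for the line differences of the 4 h combination and 24 h NMP, and for changes with time 1224, 1718 and 1591 in JJN3 and 2871, 2482 and 273 in U266 (panobinostat, combination, NMP). With a stricter filter, the U266 24 h combination against panobinostat (0), the U266 24 h non-additive effect (0) and the JJN3 5-azacytidine change with time (0) lost their calls. Median centring gave 0 for the U266 24 h non-additive effect. Quantile normalization gave 26 for U266 24 h 5-azacytidine, 35 for the U266 24 h combination against panobinostat, 1 and 0 for the non-additive effects in JJN3 at 4 h and U266 at 24 h, and 141, 148 and 241 for the 4 h line differences of panobinostat, 5-azacytidine and NMP. A constant prior variance gave 4 for the U266 24 h combination against panobinostat and 2 for its non-additive effect.

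With only the 30 libraries of the line, JJN3 5-azacytidine gave 458 at 4 h and 299 at 24 h, its change with time 10, the JJN3 combination against panobinostat 434 at 4 h and the JJN3 24 h non-additive effect 3. In U266 this gave 1407 for 5-azacytidine and 470 for NMP at 4 h, 577 and 4 for the combination against panobinostat at 4 h and 24 h, 0 for the 24 h non-additive effect, and 147 and 836 for the changes of 5-azacytidine and NMP with time.

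A replicate block, fitted because libraries of a replicate letter resembled each other, raised most counts. Against vehicle it gave 1831 and 1304 for JJN3 5-azacytidine at 4 h and 24 h, 1810 and 183 for U266 5-azacytidine, and 664 and 3684 for U266 NMP. The combination against panobinostat gave 1717 and 4491 in JJN3 and 739 and 37 in U266, and the non-additive effect 577 in JJN3 at 24 h and 1 and 3 in U266. The line differences gave 830, 876, 1899 and 1056 at 4 h (panobinostat, 5-azacytidine, combination, NMP) and 437 and 2556 at 24 h (5-azacytidine, NMP). The changes with time gave 3625, 66, 4633 and 4070 in JJN3 and 282 and 1197 in U266 (5-azacytidine, NMP).

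With voom, U266 24 h 5-azacytidine had 19 calls, the U266 24 h combination against panobinostat 3, its non-additive effect 0, the 4 h panobinostat line difference 170 and the JJN3 5-azacytidine change with time 4. With only the libraries compared, the JJN3 24 h combination had 3149, its comparison with panobinostat 0, its non-additive effect 0, its line difference 2263 and its change with time 476. Of the 169 list calls, 6 were kept with an estimated correlation, 13 with that and a replicate block, 169 with the block alone, 136 with fry (33 lost), 167 with median centring and, of 168, 143 with a stricter filter (25 lost).

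Leaving out 1 library at a time gave these lowest and highest counts. JJN3 at 4 h: panobinostat 2123 to 4044, 5-azacytidine 228 to 711, combination 2572 to 4148, NMP 1719 to 2921, non-additive 0 to 1, combination against panobinostat 167 to 842. U266 at 4 h: 1644 to 2719, 358 to 828, 2589 to 3513, 156 to 256, 0 to 2 and 97 to 174. JJN3 at 24 h: panobinostat 3836 to 6413, 5-azacytidine 281 to 472, non-additive 20 to 2329, combination against panobinostat 679 to 5809. U266 at 24 h: 5-azacytidine 14 to 30, NMP 1460 to 2116, non-additive 0 to 1, combination against panobinostat 0 to 18. Line differences at 4 h: panobinostat 97 to 500, 5-azacytidine 101 to 220, combination 397 to 1166, NMP 216 to 647, and at 24 h 5-azacytidine 53 to 104 and NMP 597 to 1395. Changes with time: JJN3 5-azacytidine 9 to 31 and combination 2078 to 4859, U266 5-azacytidine 23 to 107 and NMP 209 to 572.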

Other observations

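The comparison of NMP with panobinostat across lines was among the tests chosen only after the results were seen. NMP in one line and panobinostat in the other, which share no libraries, moved many of the same genes at 24 h. JJN3 NMP and U266 panobinostat shared 1086 higher genes (691 if independent) and 1636 lower genes (698.4), and U266 NMP and JJN3 panobinostat 376 (218.8) and 615 (205.8).

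NMP and panobinostat might share part of their late response. MYC was not seen to be part of it: panobinostat left it uncalled at 24 h (-0.17 in JJN3 and 0.46 in U266), which does not exclude a small change. Independent responses predict as many genes called in opposite as in the same direction in these comparisons without shared controls. The same direction exceeded the opposite by 4.12 times for JJN3 NMP with U266 panobinostat (2722 and 660 genes, 1389.8 opposite if independent) and 5.11 times for U266 NMP with JJN3 panobinostat (991 and 194, 425.2 opposite if independent). A general stress or arrest response to any toxic agent would give the same excess and remains open, and 5-azacytidine was not compared in this way.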
